A study of Mus musculus with 24 samples.

How the data were processed

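RNA was sequenced from mouse lumbar dorsal root ganglia in 24 libraries, 3 for each of 8 groups named in the sample labels. These were embryonic ganglia at E12.5 and E17.5, adult L4 and L5 ganglia after a peripheral lesion or sham surgery, and adult ganglia dissociated, plated on laminin and collected at 6, 12, 24 and 36 h. Cells were isolated by sorting and lysed in Qiazol, and libraries were made from 10 ng of total RNA with a TruSeq V2 kit, per the labels' protocols. The same text is attached to all libraries, and whether sorting applied to the embryonic and operated ganglia is not stated. Reads were aligned with TopHat to mm10, per the submitters' processing notes. Aligner version, annotation, counting tool and read filters are not given in the sources used here. The interval between lesion and collection is not given either, and it was not assumed.

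The deposited table held 1 signal value per gene and library, for 20782 genes, which the authors had normalized by dividing read counts by 1 factor per library. How the factors were computed is not stated in the labels, and the division itself was read from the values. In each column the low values were multiples of 1 step, and with that step 339631 values of up to 1000 reads were checked for whole reads. All of them (100%) were whole within a tolerance of 0.1. Before the data were examined, 1 test had been written for raw counts and 1 for normalized values such as FPKM. The unit found differed from both, as the values were normalized but gave back whole reads. It was treated as normalized, so limma was used and count tests on the recovered reads became alternatives. In 68 genes 1 to 3 of the values at E12.5 equalled a trimmed mean over all libraries, as described among the other observations. All 24 columns were mapped to a sample through the sample descriptions, with 0 left over, and 166 genes were at 0 in every library.

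Recovered depth ran from 3.10 to 25.7 M reads per library, with means per group of 15.9 M at E12.5, 10.7 M at E17.5, 17.2 M after sham surgery and 14.9 M after lesion. In culture the means were 14.7, 15.3, 14.9 and 9.89 M in order of time. Median ratios between libraries were 1.01 to 1.02, so no further scaling was applied. Values behind few reads, such as 24 reads for Cacna2d2 in the shallowest cultures, carry a large counting error. SD and SE reflect the spread between libraries, and floors given for genes at 0 in a group cover counting error only. How reads shared by near-identical genes were counted is not given, so values of families such as Hbb-b1 and Hbb-bs, Mrgpra and Mrgprx receptors, and Hsd3b genes are uncertain.

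Tests used limma 3.58.1 in R 4.3.3 on log2(value + 1), with eBayes set to trend and robust. A gene was tested where at least 3 libraries of the fit had a value of at least 10. Each experiment was fitted with its own libraries, without covariates. P-values were adjusted by Benjamini-Hochberg over the genes of a fit, with a threshold of 0.05. The comparisons were E17.5 minus E12.5, lesion minus sham and, in culture, an F test over the 4 times and the differences between times. Groups were called not overlapping where every library of 1 group lay above every library of the other. For the opposite directions at E17.5 and after lesion, genes called in both were counted, with the number expected of independent lists. The 23 gene lists and 9 lists of cell type markers were written before the data were examined, and so were the groups, tests, thresholds and first alternatives. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with p-values adjusted over the lists of a comparison. Camera with a correlation estimated per list and fry served as alternatives. Positions were taken from GENCODE M21.

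Genes named in the text followed a rule written before the data were examined. It took the Cacna2d genes, and in each comparison the 8 largest rises and 8 largest falls among called genes with groups that did not overlap and a higher mean of at least 100.0, leaving out symbols of uncharacterised genes. It further took up to 2 rises and 2 falls per list, the 5 largest transient peaks and troughs in culture, and the 8 genes of each opposite set with the largest smaller change. Named genes outside this rule, in the other observations, were chosen after their values had been seen. Some genes the rule took are not reported here.

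The tests were run on simulated counts with 1.5-fold, 2-fold and 4-fold changes planted before they were run on the data. Limma recovered 10.6%, 67.2% and 96.9% of them for the embryonic design over 14408 genes, 76.1%, 92.5% and 100% for the lesion design over 14430 genes, and 24.2%, 77.6% and 93.8% for the culture design over 14806 genes. Of the calls, 3.36%, 1.11% and 5.15% were false, against 5.74%, 1.67% and 7.59% with edgeR and 10.3%, 1.70% and 8.97% with DESeq2. Camera called the planted list in all 3 designs, and 1, 0 and 0 of 20 lists without change. Genes were simulated independently of each other, and few were changed. The simulation therefore does not show how camera at the preset correlation behaves on lists of correlated genes. The regrouped libraries, given among the other observations, bear on this question.

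Alternatives covered rescaling, the added constant, filters, 1 fit of all 24 libraries, moderation, a library series covariate for the lesion fit, leaving out each library, and a 2-fold limit. Whole reads were also tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. EdgeR called 4535 genes higher and 4747 lower at E17.5, 3100 and 2973 after lesion, 4131 and 3690 at 36 h, and 7233 over time. DESeq2 called 4668 and 4491, 2832 and 2568, 3855 and 4014, and 7683. Thinning to equal depth, leaving out libraries under 5 M reads and leaving out genes by their values were added after the data had been seen. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures.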

Results

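RNA of mouse lumbar dorsal root ganglia, which hold the cell bodies of sensory neurons, was measured in 24 sequencing libraries that fell into 8 groups of 3. Embryonic ganglia were taken at E12.5 and E17.5. Adult L4 and L5 ganglia came from animals with a peripheral lesion or with sham surgery, and adult lumbar ganglia were also dissociated, plated on laminin and collected after 6, 12, 24 and 36 h. The protocol text attached to all libraries names cell sorting, but whether it applied to the embryonic and operated ganglia is not stated, so these values may describe sorted cells or whole ganglia. Depth was 13.6 to 18.3 M reads at E12.5 and 3.10 to 24.3 M at E17.5. It was 12.7 to 21.8 M after sham surgery, 7.45 to 21.0 M after lesion, and 3.65 to 22.5, 3.14 to 24.0, 4.57 to 25.7 and 7.08 to 12.3 M at the 4 culture times in order. Correlations between replicates on the log2 scale ran from 0.956 to 0.991, and no pair differed by as little as sampling noise (lowest chi-square per degree of freedom 4.64). At E12.5, replicate 3 stood further from replicates 1 and 2 (43.7 and 40.3 per degree of freedom) than these from each other (10.4). In culture, replicate 1 at 12 h correlated less with the others (0.963 and 0.962) than these with each other (0.988). The same held for replicate 2 at 36 h (0.960 and 0.962, against 0.982). Both were the shallowest library of their time. Principal component 1 carried 47.1% and component 2 carried 22.3% of the variance over 15935 genes. Values below are normalized read counts as mean ± SD of 3 libraries, and changes are log2 differences ± SE on the log2(value + 1) scale, which understates changes of low genes. Genes said to rise or fall passed limma at an adjusted p of 0.05. The libraries of a group are not tied to separate animals in the labels, so p-values reflect the spread between these samples, which may be technical.

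The alpha2delta genes encode auxiliary subunits of voltage-gated calcium channels that bring the channel to the membrane, and the series title concerns Cacna2d2 and axon regeneration. Cacna2d2 was higher in late embryonic ganglia than in any other group and fell stepwise in culture. It rose from 314 ± 90.8 at E12.5 to 949 ± 116 at E17.5, a log2 change of 1.63 ± 0.22 (limma adjusted p = 2.2e-04). After lesion it stood at 222 ± 29.4 against 324 ± 12.0 after sham surgery, a change of -0.55 ± 0.11 (adjusted p = 0.00126). In culture it went from 215 ± 14.9 at 6 h to 119.7 ± 26.3 at 12 h, 68.1 ± 7.94 at 24 h and 63.7 ± 17.7 at 36 h. The change over the whole course was -1.77 ± 0.23 (adjusted p = 1.3e-05). Falls from 6 to 12 h (adjusted p = 0.0245) and from 12 to 24 h (adjusted p = 0.0355) and no call from 24 to 36 h (log2 change -0.12 ± 0.23, adjusted p = 0.814). The lowest read number behind these values was 24, in the shallow replicates 1 of the 12 h and 24 h cultures. The fall after lesion rests on the spread within lesion and sham libraries. With 1 spread estimated over all 24 libraries its adjusted p was 0.0618, the highest of a range from 1.1e-04 to 0.0618 over the alternatives. Whether Cacna2d2 changed differently in the 3 comparisons was not tested. General neuron markers had median log2 changes of 2.25 at E17.5, -0.09 after lesion and -0.54 at 36 h in culture. Whether the Cacna2d2 changes follow the share of neurons in the samples was not tested.

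**Figure D1:**
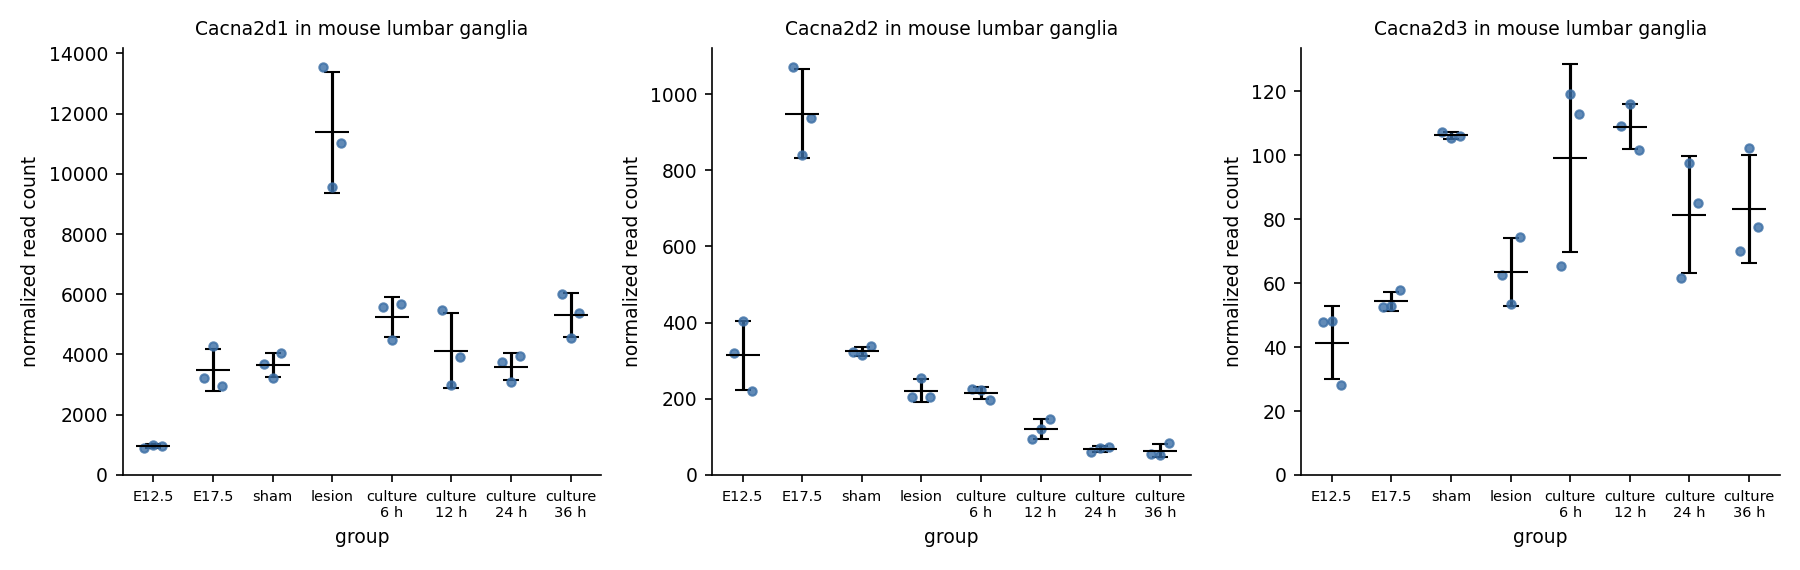
Normalized read count (vertical axes, linear and starting at 0) of Cacna2d1, Cacna2d2 and Cacna2d3 in the 8 groups (horizontal axes); points are the 3 libraries of a group, horizontal lines the means and bars the SD. Cacna2d2 was at 949 ± 116 at E17.5 and 63.7 ± 17.7 at 36 h in culture, while Cacna2d1 was at 11377 ± 2016 after lesion.

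Cacna2d1, the most abundant member of the family in every group and a binding site of gabapentin, also rose between the embryonic ages, but rose after lesion, where Cacna2d2 fell. The 2 genes were not compared by a test. Cacna2d1 rose from 959 ± 52.8 to 3487 ± 697 between the embryonic ages (log2 change 1.84 ± 0.15, adjusted p = 1.4e-05) and from 3650.3 ± 404 to 11377 ± 2016 after lesion (log2 change 1.63 ± 0.12, adjusted p = 4.1e-06). In culture it was lower at 24 h than at 6 h (3595 ± 445 against 5253 ± 671, adjusted p = 0.0292), while the other steps and the whole course from 6 to 36 h were not called (5322 ± 733 at 36 h against 5253 ± 671 at 6 h, adjusted p = 0.944). Cacna2d3 fell after lesion (63.6 ± 10.6 against 106 ± 0.999, adjusted p = 0.00198) and was not called between the ages (log2 change 0.43 ± 0.27, adjusted p = 0.203) or across the culture (-0.22 ± 0.26, adjusted p = 0.501). Cacna2d4 lay below the expression minimum, with group means of at most 3.02. In the mouse mm10 annotation of GENCODE M21 all 4 genes are protein coding. Cacna2d1 lies on chromosome 5 from 15934691 to 16374511 and Cacna2d2 on chromosome 9 from 107399612 to 107529343, both on the plus strand. Cacna2d3 lies on chromosome 14 from 28904943 to 29721864 on the minus strand and Cacna2d4 on chromosome 6 from 119236526 to 119352407 on the plus strand.

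The embryonic comparison asks which transcripts changed between E12.5, when sensory axons are growing out, and E17.5. Scn10a and Scn11a, the sodium channels of small pain-sensing neurons, rose, as did the itch receptor Mrgprx1. Fgf15, a growth factor of the early neural tube, and the homeobox genes Barhl2 and Irx1 fell until no read was left. Rrm2, which makes deoxynucleotides for replication, fell together with the other listed genes of dividing cells. Scn11a and Scn10a went to 4123 ± 418 from 16.5 ± 10.7 and to 13217 ± 1766 from 96.5 ± 33.4. Mrgprx1 reached 3913 ± 196 at E17.5 from a level near 0, and Kcnk18, a background potassium channel, went to 533 ± 102 from 0.481 ± 0.832. Other large rises were those of the matrix genes Ibsp, Aspn and Col28a1 (log2 changes 9.65 ± 0.30, 8.76 ± 0.34 and 8.01 ± 0.34), of Tmem72 (8.83 ± 0.46) and of Tyrp1, a pigment cell gene (8.48 ± 0.40). Fgf15, Barhl2 and Irx1 were at 0 in all 3 E17.5 libraries, at least 544-fold, 356-fold and 280.5-fold lower against a floor of 3 counts over the group. Hsd3b6, a steroid dehydrogenase, was likewise at least 134-fold lower. These bounds rest mostly on replicate 1, the deepest E17.5 library at 24.3 M reads. Uncx, another homeobox gene, fell by 8.23 on the log2 scale, and Slc18a3, the vesicular acetylcholine transporter, and Gad2, which makes GABA, changed by -6.59 ± 0.52 and -6.56 ± 1.30. Hemgn, expressed in blood precursors, changed by -6.52 ± 0.99. By limma 4524 of 14550 genes tested were higher and 4636 lower at E17.5, and in 69.8% of the genes the groups did not overlap, against 10% by chance.

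The library numbers of the 2 ages form separate series, so age and library series cannot be told apart. In 68 genes 1 to 3 of the E12.5 values equal a trimmed mean over all 24 libraries, and without these genes 4509 were higher and 4636 lower. Markers of other tissues moved with age. Of 51 genes known from spinal cord neurons and their precursors, a list written after the first results were seen, 32 passed the filter. Of these 27 were lower at E17.5, with a median of -3.76 over the 22 not looked at before. The filter leaves out genes absent at both ages. Genes of the fixed lists are given below with camera, a test of a list against all other genes. It called 19 of 32 lists at a preset correlation between genes, and with the correlation estimated per list it called 0, with 8 at an unadjusted p below 0.05, while fry called 24. Counts adjusted over the list alone were the same as those over all genes except where given.

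Sodium and potassium channel genes rose as groups. Of the voltage-gated sodium channel subunits, 12 of 14 rose, 1 fell and 1 was not called (median log2 change 3.08, camera adjusted p = 2.1e-05 and adjusted p = 0.187 with an estimated correlation). Potassium channels followed, of which 33 of 40 rose, 1 fell and 6 were not called, while 35 rose and 1 fell adjusted over the list alone (median log2 change 2.52, camera adjusted p = 3.8e-10 and adjusted p = 0.187 with an estimated correlation). Kcnc4 changed by 5.62 ± 0.29 and Kcnn3, a calcium-activated channel, by -1.41 ± 0.27. Among calcium channel subunits, 11 of 21 rose, 4 fell and 6 were not called (median log2 change 0.64, camera adjusted p = 0.0749). Cacna1b, the pore of N-type channels, rose to 2756 ± 282 from 552 ± 128, and Cacna1g, a low-threshold channel, fell to 133 ± 26.3 from 786 ± 274. Genes of the presynaptic vesicle and active zone were near uniform in direction, as 46 of 49 rose and 3 were not called (median log2 change 2.42, camera adjusted p = 1.4e-16 and adjusted p = 0.189 with an estimated correlation). Cplx1 and Sv2b, which act in vesicle release, changed by 4.60 ± 0.17 and 4.00 ± 0.13. For synaptic adhesion and the postsynaptic density, 23 of 40 rose, 9 fell and 8 were not called (median log2 change 0.76, camera adjusted p = 0.0224 and adjusted p = 0.476 with an estimated correlation). That list was not called without E12.5 replicate 3. Cadm2, an adhesion gene, changed by 3.68 ± 0.21, and Lrrc4b and Cbln1 by -2.64 ± 0.35 and -1.96 ± 0.18. Of the glutamate and GABA receptor genes, 23 of 34 rose, 3 fell and 8 were not called, while 24 rose and 3 fell adjusted over the list alone (median log2 change 1.98, camera adjusted p = 2.8e-05 and adjusted p = 0.207 with an estimated correlation). Grik1, a kainate receptor subunit, reached 5458 ± 88.1 against 44.1 ± 1.95 at E12.5, and Grin2c changed by -5.05 ± 0.64.

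Genes that mark classes of sensory neurons rose as well. In the nociceptor and itch list, 20 of 21 rose and 1 fell (median log2 change 4.06, camera adjusted p = 5.8e-10 and adjusted p = 0.187 with an estimated correlation). Mrgprd, a receptor of non-peptidergic nociceptors, rose to 1211 ± 92.0 from 9.33 ± 4.42, and Sst, a peptide of itch neurons, fell to 6.20 ± 6.85 from 233 ± 93.9. For mechanoreceptors and proprioceptors, 18 of 27 rose, 4 fell and 5 were not called (median log2 change 1.41, camera adjusted p = 9.0e-04 and adjusted p = 0.189 with an estimated correlation). Pvalb, a calcium buffer of proprioceptors, and Spp1 changed by 6.54 ± 0.29 and 6.17 ± 0.23, and the homeobox gene Shox2 by -2.67 ± 0.66. Of the neurofilament and mature axon genes, 19 of 22 rose, 2 fell and 1 was not called (median log2 change 2.07, camera adjusted p = 2.1e-06 and adjusted p = 0.237 with an estimated correlation). Thy1, a surface protein of mature neurons, and Cntnap1, of the paranodal junction, changed by 5.88 ± 0.41 and 5.20 ± 0.27. Ina, the neurofilament of young neurons, fell to 2849 ± 117 from 6157 ± 1469.5. Regeneration-associated genes went both ways, since 22 of 40 rose, 7 fell and 11 were not called (median log2 change 1.04, camera adjusted p = 0.00216 and adjusted p = 0.189 with an estimated correlation). Cd44, a hyaluronan receptor, and the peptide gene Gal changed by 5.36 ± 0.23 and 4.93 ± 0.32, while the protease Ecel1 and the transcription factor Sox11 changed by -5.94 ± 0.71 and -3.55 ± 0.22. Growth cone and neurite cytoskeleton genes had no common direction, as 18 of 46 rose, 14 fell and 14 were not called (median log2 change 0.12, camera adjusted p = 0.410). Stmn2 and Arpc1b changed by 2.32 ± 0.15 and 2.09 ± 0.15, and Dpysl4 and Marcksl1 by -2.27 ± 0.31 and -2.22 ± 0.14.

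Every tested cell cycle gene fell between E12.5 and E17.5, as 50 of 50 fell (median log2 change -2.29, camera adjusted p = 4.2e-18 and adjusted p = 0.189 with an estimated correlation). Rrm2 went to 231 ± 42.1 from 1984 ± 374, and Gmnn, an inhibitor of replication licensing, to 17.9 ± 12.6 from 147 ± 6.83. Neurogenesis factors were split, as 14 of 41 rose, 17 fell and 10 were not called (median log2 change -0.26, camera adjusted p = 0.525). These counts and the median, which is the value of Neurod1, rest in part on the trimmed-mean values named above. Hes5 rose with such values in all 3 E12.5 libraries. Neurod1, Insm1, Nhlh1 and Dll3 held them in some E12.5 libraries and were not called, and Neurog1 and Neurog2 held them and were not tested. Without the genes holding such values the list was not called either. Insm2 and Prrxl1 changed by 4.12 ± 0.33 and 3.52 ± 0.40, and the Notch ligand Dll1 and the neuronal factor Nhlh2 by -4.18 ± 0.34 and -3.98 ± 0.30. Of the axon guidance genes, 17 of 56 rose, 24 fell and 15 were not called (median log2 change -0.28, camera adjusted p = 0.128). These counts rest in part on trimmed-mean values too. Dcc rose with such values in all 3 E12.5 libraries. Sema3a, which was not called, held one in E12.5 replicate 3 (15.9, against 836 and 877 in replicates 1 and 2). Sema4f and Epha6 changed by 3.57 ± 0.18 and 2.90 ± 0.31, and the ephrin receptors Epha3 and Ephb1 by -3.16 ± 0.14 and -3.06 ± 0.18. Among immediate early genes, 12 of 27 rose, 8 fell and 7 were not called (median log2 change 0.36, camera adjusted p = 0.525). Egr3 and Ier3 changed by 3.36 ± 0.63 and 2.66 ± 0.25 and Btg2 by -3.02 ± 0.24. Of the heat shock genes, 9 of 20 rose, 2 fell and 9 were not called, while 8 rose and 1 fell adjusted over the list alone (median log2 change 0.33, camera adjusted p = 0.0878). The small heat shock genes Cryab and Hspb8 changed by 4.19 ± 0.45 and 4.06 ± 0.14. The unfolded protein and integrated stress response list was not called, and in it 9 of 32 rose, 8 fell and 15 were not called (median log2 change 0.14, camera adjusted p = 0.921). Asns, which makes asparagine, and Sdf2l1 changed by 2.18 ± 0.14 and -1.60 ± 0.21.

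Metabolic genes rose with age in part. Of the oxidative phosphorylation genes, 23 of 48 rose and 25 were not called (median log2 change 0.51, camera adjusted p = 5.4e-04 and adjusted p = 0.221 with an estimated correlation). Atp5o and Cox6c changed by 1.24 ± 0.21 and 1.22 ± 0.22. For cholesterol biosynthesis, 18 of 26 rose, 1 fell and 7 were not called (median log2 change 0.61, camera adjusted p = 0.00297 and adjusted p = 0.476 with an estimated correlation). Tm7sf2 changed by 1.80 ± 0.23 and Srebf2, the regulator of the pathway, by -0.60 ± 0.17. In glycolysis, 10 of 21 rose, 5 fell and 6 were not called (median log2 change 0.46, camera adjusted p = 0.0749). The brain isoforms Aldoc and Eno2 changed by 5.32 ± 0.21 and 4.72 ± 0.15 and Hk2 by -2.34 ± 0.22. Neurotrophic factors and receptors rose on balance, as 19 of 34 rose, 7 fell and 8 were not called (median log2 change 1.03, camera adjusted p = 0.00703 and adjusted p = 0.382 with an estimated correlation). Fgf1 stood at 2861 ± 54.4 against 50.01 ± 16.7. Of the cytokine and inflammation genes, 6 of 13 rose, 2 fell and 5 were not called (median log2 change 0.63, camera adjusted p = 0.243). Il34 changed by 3.19 ± 0.57 and Vcam1 by -1.75 ± 0.18. For integrins and matrix proteases, 22 of 40 rose, 6 fell and 12 were not called (median log2 change 0.76, camera adjusted p = 0.00567 and adjusted p = 0.476 with an estimated correlation). The collagenase Mmp13 changed by 7.42 ± 0.42 and Adamts4 by -1.86 ± 0.26.

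Cell type markers moved beside these groups. Of the general neuron markers, 14 of 17 rose, 1 fell and 2 were not called (median log2 change 2.25, camera adjusted p = 1.1e-05 and adjusted p = 0.212 with an estimated correlation), led by Avil at 4209 ± 570.4 against 26.5 ± 5.89. Myelinating Schwann cell markers rose, as 13 of 15 rose and 2 were not called (median log2 change 1.95, camera adjusted p = 1.1e-04 and adjusted p = 0.189 with an estimated correlation). The myelin genes Mal and Cldn19 changed by 6.11 ± 0.18 and 3.98 ± 0.29. For satellite glia, 11 of 19 rose, 3 fell and 5 were not called, while 11 rose and 4 fell adjusted over the list alone (median log2 change 1.70, camera adjusted p = 0.0191 and adjusted p = 0.212 with an estimated correlation). S100b changed by 5.70 ± 0.28 and the precursor gene Sox2 by -3.21 ± 0.40. Among fibroblast and meningeal markers, 14 of 21 rose, 3 fell and 4 were not called, while 15 rose and 3 fell adjusted over the list alone (median log2 change 2.27, camera adjusted p = 0.00234 and adjusted p = 0.476 with an estimated correlation). Mfap5 and Igfbp6 changed by 6.10 ± 0.38 and 6.08 ± 0.35. Of the macrophage markers, 8 of 19 rose and 11 were not called, while 7 rose adjusted over the list alone (median log2 change 0.66, camera adjusted p = 0.0370 and adjusted p = 0.476 with an estimated correlation). Lyz2 changed by 1.52 ± 0.22. This list was not called without E12.5 replicate 1, E12.5 replicate 2 or E17.5 replicate 1. Endothelial markers were split, as 4 of 19 rose, 4 fell and 11 were not called, while 3 rose and 2 fell adjusted over the list alone (median log2 change 0.02, camera adjusted p = 0.891). Ly6c1 changed by 3.47 ± 0.51 and Cldn5 by -1.73 ± 0.24. For pericytes and smooth muscle, 5 of 12 rose, 2 fell and 5 were not called (median log2 change 0.50, camera adjusted p = 0.364). Myh11 changed by 3.99 ± 0.56 and Notch3 by -2.10 ± 0.18. Erythroid markers were also split, as 5 of 12 rose, 5 fell and 2 were not called (median log2 change 0.45, mean -0.15, test upward, camera adjusted p = 0.594). Adult globin Hbb-b1 changed by 4.55 ± 0.29 and Rhag by -3.93 ± 0.69. Among skeletal muscle markers, 5 of 11 rose and 6 were not called, while 4 rose adjusted over the list alone (median log2 change 1.25, camera adjusted p = 0.193). Ckm changed by 4.73 ± 0.90.

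The adult comparison asks which transcripts a peripheral lesion, a state in which sensory neurons can regrow axons, changed against sham surgery. Sprr1a, a cornifin known from regenerating axons, Atf3, a transcription factor of injured neurons, and the neuropeptide Npy rose after lesion. Csf1, a growth factor of macrophages, rose together with macrophage genes such as Trem2. The serotonin receptor genes Htr3a and Htr3b, expressed in subsets of mature sensory neurons, fell. Sprr1a went to 19137 ± 4545 from 469 ± 153. Npy went to 428 ± 187 from 13.0 ± 2.16, and Atf3 to 9207 ± 1995 from 557 ± 28.8. Gpr151 and Cckbr, both receptors, and the protease Ecel1 changed by 4.22 ± 0.20, 4.55 ± 0.14 and 4.21 ± 0.17, and Igfn1, the growth factor Fgf3 and the activin-type receptor Acvr1c by 5.00 ± 0.25, 4.84 ± 0.26 and 4.71 ± 0.38. Among the falls were Htr3a (526 ± 133 against 1885 ± 46.4) and Htr3b (79.4 ± 12.0 against 276 ± 4.55), the angiotensin receptor Agtr1b (-2.01 ± 0.23) and the calcium buffer Calb2 (-1.97 ± 0.14). Fabp7, a lipid carrier of satellite glia, Glb1l2, Vwc2l and Calml4 changed by -1.66 ± 0.13, -1.53 ± 0.14, -1.51 ± 0.13 and -1.46 ± 0.15. By limma 3043 of 14556 genes were higher and 2947 lower after lesion, and the groups did not overlap in 52.5% of the genes, against 10% by chance. Of the genes called, 578 and 194 changed at least 2-fold. The interval between lesion and collection is not stated in the labels. With 1 spread over all 24 libraries, 1541 genes were higher and 1052 lower. Camera called 16 of 32 lists at the preset correlation, and 0 with an estimated correlation, with 2 at an unadjusted p below 0.05 and 17 by fry.

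Regeneration-associated, growth cone and axon guidance genes rose on balance after lesion. Of the regeneration-associated genes, 35 of 40 rose, 2 fell and 3 were not called, while 36 rose and 2 fell adjusted over the list alone (median log2 change 1.94, camera adjusted p = 3.0e-21 and adjusted p = 0.354 with an estimated correlation). The falls were those of Scg2, a granin (5622 ± 582 against 10782 ± 615), and Bdnf, a neurotrophin (814 ± 56.1 against 1117 ± 167). For the growth cone and neurite cytoskeleton, 28 of 46 rose, 4 fell and 14 were not called (median log2 change 0.34, camera adjusted p = 8.2e-06 and adjusted p = 0.472 with an estimated correlation). Stmn4 and Tubb6, which act on microtubules, changed by 2.45 ± 0.28 and 2.35 ± 0.15 and the actin-binding Pfn2 by -0.35 ± 0.07. Axon guidance genes rose on balance, as 25 of 55 rose, 9 fell and 21 were not called, while 25 rose and 10 fell adjusted over the list alone (median log2 change 0.23, camera adjusted p = 0.00252 and adjusted p = 0.478 with an estimated correlation). Sema6a stood at 2646 ± 500.3 against 277 ± 43.5 and Draxin at 403 ± 88.0 against 54.3 ± 14.4. Neurofilament and mature axon genes were split, as 5 of 21 rose, 9 fell and 7 were not called, while 6 rose and 9 fell adjusted over the list alone (median log2 change -0.01, camera adjusted p = 0.315). The neurofilament genes Nefh and Nefl changed by -0.81 ± 0.09 and -0.73 ± 0.07 and Ank3, of the axon initial segment, by 0.55 ± 0.07. Of the neurogenesis factors, 7 of 36 rose, 11 fell and 18 were not called (median log2 change 0.05, mean 0.04, test downward, camera adjusted p = 0.968). Sox11 and Klf6 changed by 2.90 ± 0.19 and 1.15 ± 0.09. Most cell cycle genes were not called, as 1 of 40 rose, 3 fell and 36 were not called, while 1 rose adjusted over the list alone (median log2 change 0.07, camera adjusted p = 0.759). Prc1, which acts in cytokinesis, changed by 1.79 ± 0.16. Among neurotrophic factors and receptors, 13 of 34 rose, 9 fell and 12 were not called (median log2 change 0.19, camera adjusted p = 0.315). Clcf1 changed by 2.28 ± 0.41 and Ntf3 by -1.45 ± 0.30. Of the immediate early genes, 17 of 25 rose and 8 were not called, while 18 rose adjusted over the list alone (median log2 change 0.65, camera adjusted p = 5.5e-08 and adjusted p = 0.354 with an estimated correlation). Fosl2 changed by 1.29 ± 0.13.

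Sodium and potassium channel and sensory receptor genes fell on balance after lesion, while calcium channel and synaptic lists were split. Of the sodium channel subunits, 9 of 14 fell and 5 were not called, while 2 rose and 10 fell adjusted over the list alone (median log2 change -0.31, camera adjusted p = 0.00265 and adjusted p = 0.472 with an estimated correlation). Scn1a stood at 1879 ± 177 against 3612 ± 213. Among potassium channels, 3 of 41 rose, 25 fell and 13 were not called, while 5 rose and 27 fell adjusted over the list alone (median log2 change -0.40, camera adjusted p = 1.7e-06 and adjusted p = 0.472 with an estimated correlation). Kcng4 and Kcnh7 changed by -1.41 ± 0.11 and -1.23 ± 0.10 and Kcnmb4, a subunit of calcium-activated channels, by 0.80 ± 0.13. Calcium channel subunits had no common direction, as 4 of 20 rose, 3 fell and 13 were not called, while 3 rose and 3 fell adjusted over the list alone (median log2 change 0.05, camera adjusted p = 0.728). Cacna1b changed by 0.79 ± 0.08 and Cacnb4 by -0.59 ± 0.10. For glutamate and GABA receptors, 4 of 28 rose, 14 fell and 10 were not called, while 4 rose and 15 fell adjusted over the list alone (median log2 change -0.32, camera adjusted p = 0.00420 and adjusted p = 0.472 with an estimated correlation). The GABA receptor subunit Gabrb2 changed by -1.09 ± 0.09 and the kainate receptor Grik3 by 0.67 ± 0.09. Presynaptic genes were split, as 11 of 48 rose, 15 fell and 22 were not called, while 12 rose and 18 fell adjusted over the list alone (median log2 change -0.07, camera adjusted p = 0.431). Doc2b changed by 1.70 ± 0.21 and Vamp1 and Sv2b by -0.94 ± 0.08 and -0.90 ± 0.07. Of the synaptic adhesion and postsynaptic genes, 9 of 40 rose, 7 fell and 24 were not called (median log2 change -0.04, mean 0.03, test upward, camera adjusted p = 0.822). Cbln2 changed by 0.83 ± 0.12 and Slitrk4 by -0.73 ± 0.08. In the mechanoreceptor and proprioceptor list, 1 of 27 rose, 17 fell and 9 were not called, while 1 rose and 18 fell adjusted over the list alone (median log2 change -0.47, camera adjusted p = 2.2e-06 and adjusted p = 0.354 with an estimated correlation). Chodl changed by -1.80 ± 0.23. Among nociceptor and itch genes, 5 of 30 rose, 18 fell and 7 were not called, while 5 rose and 19 fell adjusted over the list alone (median log2 change -0.57, camera adjusted p = 8.1e-04 and adjusted p = 0.595 with an estimated correlation). The peptide Adcyap1 and the receptor Gfra3 changed by 0.97 ± 0.09 and 0.78 ± 0.09, and Mrgprx1 and the opioid receptor Oprd1 by -1.45 ± 0.23 and -1.36 ± 0.12.

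Energy and stress genes also moved. Of the oxidative phosphorylation genes, 38 of 48 fell and 10 were not called, while 42 fell adjusted over the list alone (median log2 change -0.52, camera adjusted p = 2.3e-11 and adjusted p = 0.472 with an estimated correlation). Ndufa1 stood at 63.1 ± 13.0 against 145 ± 50.6 and Atp5h at 175 ± 62.1 against 323 ± 52.5. For heat shock genes, 2 of 20 rose, 14 fell and 4 were not called (median log2 change -0.33, camera adjusted p = 3.2e-04 and adjusted p = 0.472 with an estimated correlation). The cochaperone Stip1 changed by -0.55 ± 0.08. Among glycolysis genes, 5 of 21 rose, 11 fell and 5 were not called, while 5 rose and 12 fell adjusted over the list alone (median log2 change -0.22, camera adjusted p = 0.0816). Slc2a1, a glucose transporter, changed by 0.87 ± 0.08 and Ldhb by -0.91 ± 0.08. In cholesterol biosynthesis, 2 of 26 rose, 8 fell and 16 were not called (median log2 change -0.11, camera adjusted p = 0.377). Hsd17b7 changed by 1.26 ± 0.11 and Pmvk by -0.45 ± 0.09. Of the unfolded protein and integrated stress response genes, 13 of 31 rose, 6 fell and 12 were not called (median log2 change 0.15, camera adjusted p = 0.0224 and adjusted p = 0.472 with an estimated correlation), a call lost without sham replicate 3. Chac1 and Sesn2, targets of that response, changed by 1.72 ± 0.15 and 1.39 ± 0.17 and Pdia6, an enzyme of protein folding, by -0.43 ± 0.09.

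Immune and matrix genes rose beside the growth genes. Among macrophage and immune markers, 22 of 24 rose and 2 were not called, while 23 rose adjusted over the list alone (median log2 change 1.17, camera adjusted p = 5.3e-12 and adjusted p = 0.354 with an estimated correlation). Trem2 and Cx3cr1, receptors of macrophages, went to 49.2 ± 11.1 from 12.0 ± 3.51 and to 464 ± 114 from 142 ± 9.79. Of the cytokine and inflammation genes, 11 of 18 rose and 7 were not called (median log2 change 0.64, camera adjusted p = 8.6e-05 and adjusted p = 0.354 with an estimated correlation). Csf1 stood at 2988 ± 672 against 407 ± 47.5, and the chemokine Ccl8 changed by 2.23 ± 0.40. For integrins and matrix proteases, 21 of 39 rose and 18 were not called (median log2 change 0.40, camera adjusted p = 1.6e-06 and adjusted p = 0.354 with an estimated correlation). Mmp16 and Adam8 changed by 2.87 ± 0.12 and 2.60 ± 0.18. Among fibroblast and meningeal markers, 9 of 20 rose and 11 were not called, while 10 rose adjusted over the list alone (median log2 change 0.41, camera adjusted p = 6.8e-04 and adjusted p = 0.472 with an estimated correlation). Col5a1 changed by 0.64 ± 0.10. Satellite glia markers were split, as 6 of 19 rose, 4 fell and 9 were not called, while 6 rose and 5 fell adjusted over the list alone (median log2 change 0.03, mean 0.01, test downward, camera adjusted p = 0.998). Aldh1l1 and Glul changed by 1.57 ± 0.19 and 0.57 ± 0.08 and S100b by -0.72 ± 0.09. General neuron markers were split too, as 6 of 17 rose, 6 fell and 5 were not called (median log2 change -0.09, mean 0.01, test downward, camera adjusted p = 0.793). Gap43, a growth cone protein, changed by 1.38 ± 0.11 and Snap25 by -0.71 ± 0.11. Few Schwann cell markers were called, as 2 of 18 rose and 16 were not called (median log2 change 0.09, camera adjusted p = 0.315). Gldn and Egr2 changed by 0.87 ± 0.11 and 0.47 ± 0.10. For endothelium, 4 of 20 rose and 16 were not called, while 3 rose adjusted over the list alone (median log2 change 0.18, camera adjusted p = 0.260), and for pericytes and smooth muscle, 4 of 13 rose, 1 fell and 8 were not called (median log2 change 0.15, camera adjusted p = 0.256). Of the erythroid markers, 1 of 10 rose, 2 fell and 7 were not called, while 1 rose and 4 fell adjusted over the list alone (median log2 change -0.14, camera adjusted p = 0.315), and of the skeletal muscle markers, 1 of 7 rose, 1 fell and 5 were not called, while 1 fell adjusted over the list alone (median log2 change -0.56, camera adjusted p = 0.463).

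The culture series asks how transcripts of plated adult neurons changed over 36 h. Mrgprd, a receptor of non-peptidergic nociceptors, and the itch receptor Mrgpra3 fell steeply after plating. Sprr1a and Ecel1, which had risen after lesion, also rose in the dish. Itga7, a subunit of a laminin receptor, rose on the laminin substrate. Mrgprd went from 3765 ± 604 at 6 h to 1869 ± 266, 217 ± 19.4 and 49.98 ± 13.7 at the later times. Sprr1a went from 29.8 ± 15.8 to 247 ± 43.8, 1611 ± 98.9 and 2979 ± 397, and Ecel1 from 54.6 ± 5.94 at 6 h to 1319 ± 304 at 36 h. Other rises were those of the chromatin protein Hmga2 (4.35 ± 0.17), the peptide receptor Qrfpr (4.45 ± 0.28), the replication gene Dtl (4.39 ± 0.34), the spindle gene Psrc1 (5.13 ± 0.53) and Tmprss5 and Lrg1 (4.80 ± 0.31 and 4.27 ± 0.48). The falls held the receptors Mrgpra3 and Mrgpra2b (-5.47 ± 0.69 and -5.94 ± 0.66), the nicotinic receptor subunit Chrna6 (-6.12 ± 0.20), the lysophosphatidic acid receptor Lpar3 (-5.12 ± 0.25), Ctxn3 (-5.60 ± 0.26) and Rgs8 (-4.94 ± 0.24). Fosb, an immediate early gene, went from 2083 ± 128 to 43.9 ± 12.3. By limma's F test 6859 of 15006 genes changed over time. At 36 h 3794 genes were higher and 3795 lower than at 6 h, and the groups did not overlap in 59.0% of the genes, against 10% by chance. Between neighbouring times 880 genes were higher and 708 lower from 6 to 12 h, 723 and 1011 from 12 to 24 h, and 166 and 232 from 24 to 36 h. Groups did not overlap in 26.5%, 30.5% and 29.5% of the genes at these steps, against 10% by chance, and the sizes of the steps were not compared by a test.

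**Figure D2:**
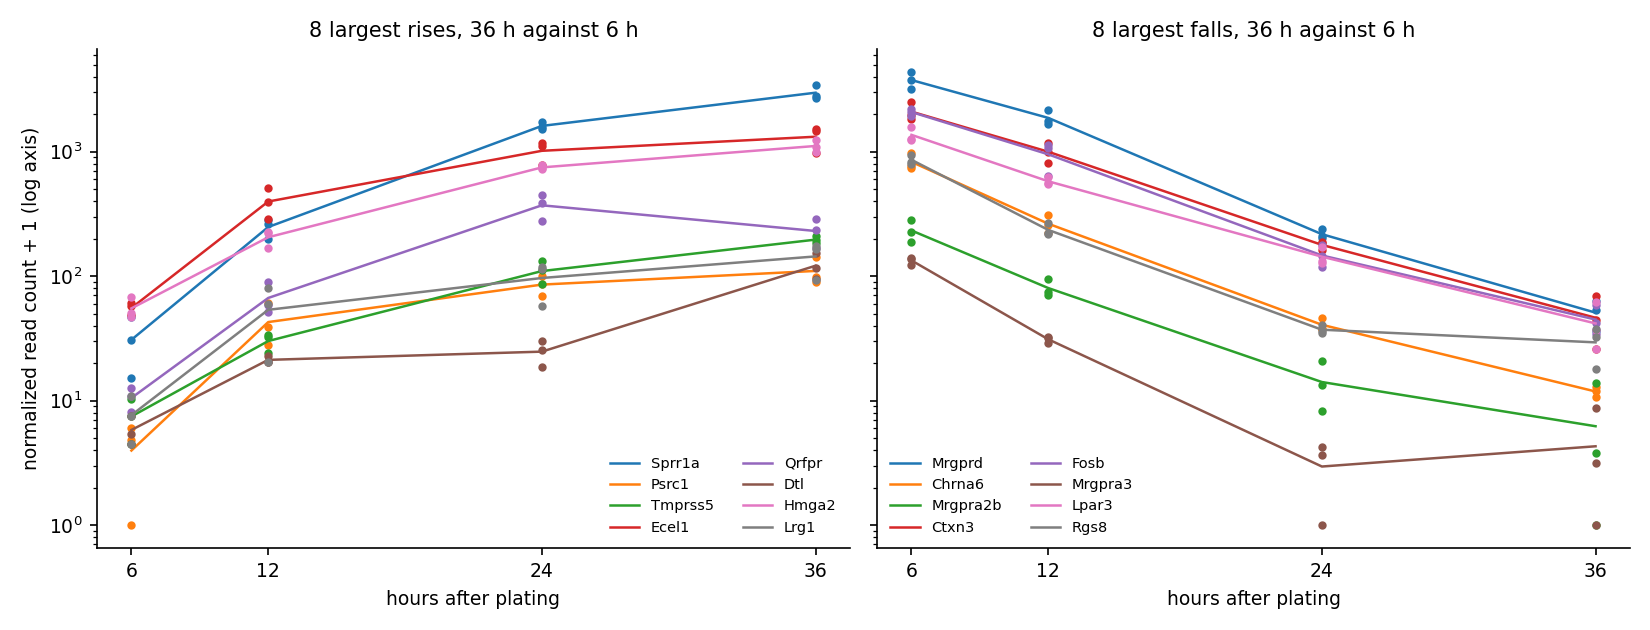
Normalized read count plus 1 (vertical axes, log scale) against hours after plating (horizontal axes) for the 8 largest rises, left, and the 8 largest falls, right, between 6 and 36 h; points are single libraries, 3 per time, and lines join the means. Mrgprd went from 3765 ± 604 at 6 h to 49.98 ± 13.7 at 36 h, and Sprr1a from 29.8 ± 15.8 to 2979 ± 397.

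Some genes had their highest or lowest mean at 12 or 24 h. They were picked for the size of this excursion in the same data. The F test asks for any change over time, so whether a middle time differs from both ends was not tested. Slfn4 had its highest mean at 12 h, 159 ± 17.2, against 56.9 ± 15.5 at 6 h and 58.1 ± 5.72 at 36 h (limma F adjusted p = 2.1e-04). The peptide gene Adm2 (adjusted p = 0.00165), the retinoic acid hydroxylase Cyp26b1 (adjusted p = 0.00429) and the mucin Muc5b (adjusted p = 3.5e-04) peaked at 12 h too, with 129.6 ± 31.3, 284 ± 62.1 and 169.7 ± 21.3. So did Pcdh15 (113 ± 32.4), a call lost when the libraries were thinned to equal depth. Dcx, a microtubule protein of young neurons, had its lowest mean at 24 h, 89.4 ± 15.3 against 356 ± 64.8 at 6 h and 269.7 ± 10.0 at 36 h (adjusted p = 6.1e-07). Tmem158 and Chst12 were lowest at 12 h, with 211 ± 24.98 and 108 ± 52.0. The proliferation marker Mki67 was lowest at 24 h (104.6 ± 28.4), as was the repair gene Brca1 (50.3 ± 17.8), whose call was lost without replicate 1 or replicate 2 of that time. Camera called 21 of 31 lists between 6 and 36 h at the preset correlation, 3 with an estimated correlation and 27 by fry.

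Sensory, channel and presynaptic genes fell in culture. In the nociceptor and itch list, 2 of 30 rose, 24 fell and 4 were not called (median log2 change -2.11, camera adjusted p = 1.2e-09 and adjusted p = 0.0433 with an estimated correlation). Mrgprd and Mrgpra3 changed by -6.23 ± 0.19 and -5.47 ± 0.69, and Gfra3, the artemin receptor, and the peptide gene Adcyap1 by 1.32 ± 0.17 and 1.08 ± 0.21. Of the sodium channel subunits, 1 of 14 rose, 11 fell and 2 were not called (median log2 change -1.59, camera adjusted p = 3.5e-06 and adjusted p = 0.0638 with an estimated correlation). Scn11a stood at 987 ± 30.8 against 9144 ± 1169.8 and Scn2b at 145 ± 30.6 against 847 ± 88.5. Among potassium channels, 3 of 41 rose, 31 fell and 7 were not called (median log2 change -1.19, camera adjusted p = 2.5e-08 and adjusted p = 0.110 with an estimated correlation). The channel-interacting genes Kcnip1 and Kcnip2 changed by -3.34 ± 0.28 and -2.96 ± 0.23. Among calcium channel subunits, 2 of 19 rose, 9 fell and 8 were not called, while 2 rose and 10 fell adjusted over the list alone (median log2 change -0.36, camera adjusted p = 0.0208 and adjusted p = 0.341 with an estimated correlation). The low-threshold channels Cacna1i and Cacna1h changed by -4.90 ± 0.39 and 0.63 ± 0.18 and Cacnb4 by -2.33 ± 0.16. For the presynaptic vesicle and active zone, 4 of 48 rose, 36 fell and 8 were not called, while 5 rose and 36 fell adjusted over the list alone (median log2 change -0.85, camera adjusted p = 2.2e-08 and adjusted p = 0.171 with an estimated correlation). Rab3c and Snap25, of the release machinery, changed by -2.05 ± 0.14 and -1.71 ± 0.17 and Bin1 by 0.63 ± 0.12. Synaptic adhesion genes were split, as 10 of 40 rose, 17 fell and 13 were not called, while 10 rose and 18 fell adjusted over the list alone (median log2 change -0.44, camera adjusted p = 0.0919). Lrrc4b and Shank2 changed by 2.95 ± 0.33 and 1.77 ± 0.35 and Lrrtm2 by -2.44 ± 0.17. Of the glutamate and GABA receptors, 4 of 29 rose, 15 fell and 10 were not called (median log2 change -0.53, camera adjusted p = 0.00146 and adjusted p = 0.128 with an estimated correlation). The kainate receptors Grik3 and Grik1 changed by 1.80 ± 0.15 and -3.42 ± 0.12. In the mechanoreceptor and proprioceptor list, 3 of 27 rose, 17 fell and 7 were not called, while 3 rose and 18 fell adjusted over the list alone (median log2 change -0.84, camera adjusted p = 0.00278 and adjusted p = 0.341 with an estimated correlation). Spp1 changed by 1.80 ± 0.18 and Th, which makes dopamine, by -2.29 ± 0.20. General neuron markers fell beside these lists, as 1 of 17 rose, 8 fell and 8 were not called (median log2 change -0.54, camera adjusted p = 0.00237 and adjusted p = 0.206 with an estimated correlation). Scn10a changed by -1.93 ± 0.12.

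Matrix, regeneration-associated and division genes rose in culture. Integrins and matrix proteases were called with an estimated correlation too, and of them 28 of 42 rose, 3 fell and 11 were not called, while 30 rose and 4 fell adjusted over the list alone (median log2 change 1.08, camera adjusted p = 3.5e-08 and adjusted p = 0.00362 with an estimated correlation). Itga7 went to 12867 ± 907 from 1971 ± 426 and Itgb4, of another laminin receptor, to 266 ± 31.1 from 25.1 ± 15.8, while the protease Plau fell to 114 ± 29.7 from 256 ± 28.0. Of the regeneration-associated genes, 21 of 42 rose, 6 fell and 15 were not called (median log2 change 0.59, camera adjusted p = 4.4e-05 and adjusted p = 0.110 with an estimated correlation). Sprr1a changed by 6.73 ± 0.28, Ecel1 by 4.55 ± 0.22 and Klf6, a transcription factor, by -0.88 ± 0.14. The growth cone and neurite cytoskeleton had no common direction, as 15 of 45 rose, 12 fell and 18 were not called, while 15 rose and 13 fell adjusted over the list alone (median log2 change -0.06, mean 0.13, test upward, camera adjusted p = 0.749). Cotl1 and Tubb6 changed by 2.12 ± 0.20 and 2.08 ± 0.17 and Pfn2 by -1.36 ± 0.11. For neurofilaments and the mature axon, 1 of 21 rose, 9 fell and 11 were not called (median log2 change -0.45, camera adjusted p = 0.0119 and adjusted p = 0.449 with an estimated correlation). Sncg and Cntnap2 changed by -1.70 ± 0.11 and -1.36 ± 0.14. Among axon guidance genes, 21 of 55 rose, 12 fell and 22 were not called, while 23 rose and 12 fell adjusted over the list alone (median log2 change 0.36, camera adjusted p = 0.0481 and adjusted p = 0.437 with an estimated correlation), a call lost on leaving out any of 5 single libraries, replicates 1 and 2 at 24 h, 2 and 3 at 36 h and 1 at 6 h. Plxnb1 and Ephb2 changed by 3.26 ± 0.28 and 2.45 ± 0.35 and Epha4 by -2.07 ± 0.31. Cell cycle genes rose on balance, as 23 of 41 rose, 1 fell and 17 were not called, while 24 rose and 1 fell adjusted over the list alone (median log2 change 0.98, camera adjusted p = 4.3e-05 and adjusted p = 0.171 with an estimated correlation). Uhrf1 and Top2a, of replicating cells, changed by 4.19 ± 0.31 and 3.75 ± 0.50 and the spindle motor Kif11 by -2.59 ± 0.34. Of the neurogenesis factors, 4 of 36 rose, 16 fell and 16 were not called (median log2 change -0.37, camera adjusted p = 0.0208 and adjusted p = 0.1002 with an estimated correlation). Dll4, a Notch ligand of vessels, changed by 2.39 ± 0.29 and Nhlh2 by -3.50 ± 0.78.

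Stress and metabolic genes moved in both directions. The unfolded protein and integrated stress response was called with an estimated correlation as well, and of its genes 18 of 32 rose, 5 fell and 9 were not called, while 18 rose and 6 fell adjusted over the list alone (median log2 change 0.41, camera adjusted p = 0.00153 and adjusted p = 0.0433 with an estimated correlation). Phgdh, which makes serine, and the disulfide isomerase Pdia4 changed by 1.91 ± 0.17 and 1.78 ± 0.10 and the stress phosphatase subunit Ppp1r15a by -0.72 ± 0.17. Of the heat shock genes, 2 of 20 rose, 12 fell and 6 were not called (median log2 change -0.47, camera adjusted p = 0.00451 and adjusted p = 0.128 with an estimated correlation). Hspb1 changed by 0.83 ± 0.15 and Hspa1b and Dnaja1 by -1.36 ± 0.31 and -1.30 ± 0.17. Cholesterol biosynthesis genes fell, as 14 of 26 fell and 12 were not called, while 16 fell adjusted over the list alone (median log2 change -0.59, camera adjusted p = 0.00112 and adjusted p = 0.0638 with an estimated correlation). Stard4 and Idi1 changed by -1.63 ± 0.15 and -1.53 ± 0.20. In glycolysis, 2 of 21 rose, 7 fell and 12 were not called (median log2 change -0.25, camera adjusted p = 0.0580). Slc2a1 changed by 1.29 ± 0.12 and Pdk1 by -1.61 ± 0.13. Of the oxidative phosphorylation genes, 1 of 48 rose, 11 fell and 36 were not called, while 1 rose and 7 fell adjusted over the list alone (median log2 change -0.25, camera adjusted p = 0.0950). Sdhc changed by 0.44 ± 0.12 and Cycs by -1.09 ± 0.19. Immediate early genes were split, as 6 of 28 rose, 8 fell and 14 were not called (median log2 change 0.14, mean -0.27, test downward, camera adjusted p = 0.755). Nr4a1 changed by 1.30 ± 0.17 and Nr4a3 by -3.18 ± 0.74. Of the neurotrophic factors and receptors, 15 of 36 rose, 11 fell and 10 were not called, while 15 rose and 12 fell adjusted over the list alone (median log2 change 0.23, camera adjusted p = 0.420). Artn and Erbb3 changed by 4.33 ± 0.56 and 3.23 ± 0.17 and Fgf13 by -3.37 ± 0.16. For cytokines and inflammation, 13 of 32 rose, 7 fell and 12 were not called, while 13 rose and 8 fell adjusted over the list alone (median log2 change 0.10, camera adjusted p = 0.169). Saa3 and Il11 changed by 3.73 ± 0.61 and 2.59 ± 0.22 and Ccl7 by -1.98 ± 0.21.

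Cell type markers moved beside the culture genes. Endothelial markers rose, as 17 of 20 rose and 3 were not called (median log2 change 1.14, camera adjusted p = 2.7e-06 and adjusted p = 0.266 with an estimated correlation). Plvap, of fenestrated endothelium, went to 1069 ± 111 from 85.6 ± 14.4 and Sox18 to 222 ± 48.5 from 26.7 ± 6.54. Among satellite glia markers, 11 of 19 rose, 4 fell and 4 were not called (median log2 change 0.78, camera adjusted p = 0.0187 and adjusted p = 0.206 with an estimated correlation). The channel gene Kcnj10 changed by 2.11 ± 0.15 and S100b by -1.46 ± 0.14. For myelinating Schwann cells, 3 of 18 rose, 4 fell and 11 were not called (median log2 change -0.29, camera adjusted p = 0.383). Cnp changed by 1.90 ± 0.16 and Drp2 by -1.21 ± 0.17. Of the macrophage markers, 9 of 21 rose, 5 fell and 7 were not called (median log2 change 0.55, camera adjusted p = 0.367). Csf1r changed by 1.99 ± 0.28 and H2-Eb1 by -2.09 ± 0.34. Among pericyte and smooth muscle markers, 6 of 12 rose and 6 were not called (median log2 change 0.59, camera adjusted p = 0.0275 and adjusted p = 0.341 with an estimated correlation). Notch3 and Kcnj8 changed by 2.62 ± 0.37 and 2.44 ± 0.35. This list call was lost without 36 h replicate 1. For fibroblasts and meninges, 7 of 19 rose, 3 fell and 9 were not called, while 8 rose and 3 fell adjusted over the list alone (median log2 change 0.33, camera adjusted p = 0.129). Postn changed by 2.22 ± 0.17 and Ogn by -2.27 ± 0.32. Erythroid markers fell, as 7 of 9 fell and 2 were not called, while 8 fell adjusted over the list alone (median log2 change -1.17, camera adjusted p = 0.0284 and adjusted p = 0.379 with an estimated correlation). Slc4a1 changed by -3.24 ± 0.83. This call was lost without 36 h replicate 3. Only 4 skeletal muscle markers were tested, too few for camera, of which 1 rose (Ttn, 1.82 ± 0.21, a call lost with 1 spread over all 24 libraries) and 3 were not called.

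**Figure D3:**
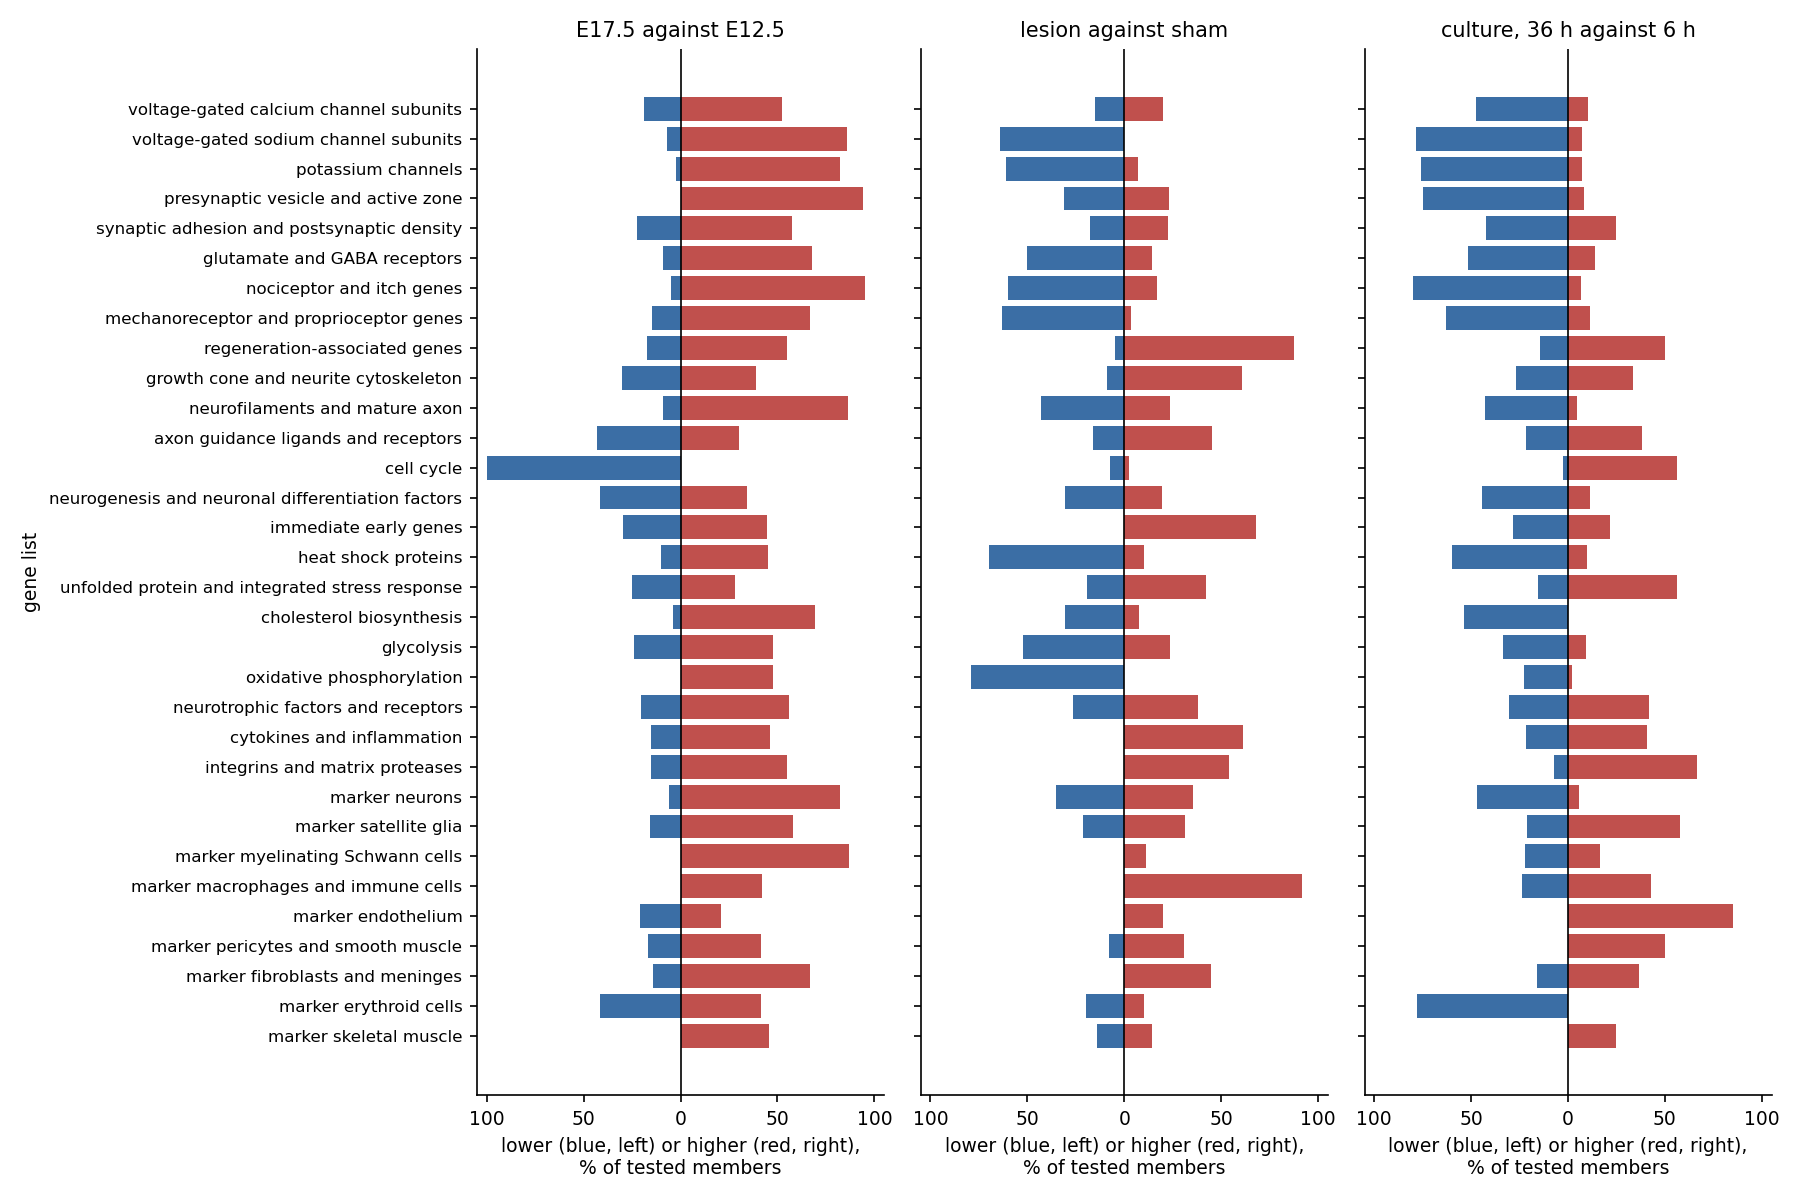
Share of the tested members of each gene list (vertical axis) that limma called lower (bars to the left) or higher (bars to the right), in percent (horizontal axes), for E17.5 against E12.5, lesion against sham and 36 h against 6 h in culture. Of the cell cycle genes 50 of 50 were lower at E17.5, of the macrophage markers 22 of 24 were higher after lesion, and of the endothelial markers 17 of 20 were higher at 36 h.

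The design also sets development against the regenerating state, and counts the genes that changed in opposite directions. The set that rose at E17.5 and fell after lesion held the serotonin receptor genes Htr3a and Htr3b, the angiotensin receptor Agtr1b and the adhesion gene Cntn6, besides Ppapdc1a, Bnc1, Vwc2l and Rassf6. Their log2 changes at E17.5 and after lesion were 5.90 and -1.87 for Htr3a, 7.97 and -1.80 for Htr3b and 5.25 and -2.01 for Agtr1b. For Ppapdc1a they were 4.09 and -1.90, for Vwc2l 3.81 and -1.51, for Bnc1 3.15 and -1.58, for Cntn6 2.73 and -1.68 and for Rassf6 3.25 and -1.50. Lesion calls of Bnc1, Cntn6 and Rassf6 were lost with 1 spread over all 24 libraries. Genes that fell at E17.5 and rose after lesion included Ecel1 (-5.94 and 4.21) and the homeobox genes En1 (-5.27 and 4.08) and Lmx1a (-5.26 and 3.52). Others were the transcription factor Sox11 (-3.55 and 2.90) and Npy (-2.86 and 4.83). Several genes named from the 2 sets were low, as no minimum level was set beyond the filter. En1 and Lmx1a had means of 25.5 and 17.2 after lesion against 0.519 and 0.679 after sham surgery. Npy had means of 16.9 at E12.5 and 1.94 at E17.5. En1 is also among the spinal cord genes that were lower at E17.5. Sez6l, Glis3 and Trp53i11 changed by -3.17 and 3.31, by -2.66 and 3.28 and by -2.63 and 3.01. Over 13840 genes tested in both, 1464 (903 expected) rose at E17.5 and fell after lesion, and 1154 (894 expected) did the reverse, where the expected number is that of independent lists. Fewer than expected moved the same way, with 778 (914 expected) up and 383 (884 expected) down in both. Cacna2d2 was in the first set, at rank 511 of 1373 named genes by the smaller of its 2 changes. Across genes, which are not independent, the changes had a Pearson r of -0.21 and a Spearman rho of -0.23. With 1 spread over all 24 libraries the opposite sets held 670 and 680 genes.

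Culture went with lesion more than with development. Between lesion and 36 h in culture, over 14207 genes, 1490 (755 expected) rose in both and 1696 (757 expected) fell in both, and the changes correlated across genes with a Pearson r of 0.46 and a Spearman rho of 0.46. Sprr1a and Ecel1 rose in both, and Htr3a and Htr3b fell in both, with log2 changes in culture of -0.87 (adjusted p = 1.1e-04) and -1.73 (adjusted p = 2.4e-05). Against development, over 13955 genes, 1993 (1112 expected) rose at E17.5 and fell in culture and 1593 (1123 expected) did the reverse (Pearson r -0.36, Spearman rho -0.35). Cacna2d2 was among 1071 genes (231 expected) of 13667 that rose at E17.5, fell after lesion and fell in culture, and 657 (226 expected) did the opposite in all 3. No libraries were shared between these comparisons.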

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

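The runs thinned to the shallowest library, without libraries under 5 M reads, without genes holding trimmed-mean values and with only genes at a mean of at least 10 after sham surgery were chosen after the data had been seen. Under all alternatives together, 271 values of the main results stayed the same, 16 moved and 1 lost its call, and no direction reversed. Of the named genes 6805 values kept their status, called or not called, and 217 lost a call. Directions were compared only where a gene was called, and not for the transient genes in culture. Of the gene lists 1227 stayed the same, 30 gained a call and 68 lost it. Genes that an alternative did not test, and those to which DESeq2 gave no adjusted p, stayed out of the totals.

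With 1 fit of all 24 libraries, 1541 genes were higher and 1052 lower after lesion, the opposite sets held 670 (higher at E17.5, lower after lesion) and 680 genes, and the Cacna2d2 change after lesion (-0.55) was not called (limma adjusted p = 0.0618, range over its alternatives 1.1e-04 to 0.0618). This fit takes the spread of all groups for the spread of lesion and sham libraries. With a change of at least 2-fold required, 3010 genes were higher and 2450 lower at E17.5, 578 higher and 194 lower after lesion, 1854 higher and 1824 lower at 36 h, 3627 changed over time, and the opposite sets held 87 and 108. That condition removes genes by construction. With the correlation estimated per list, camera called 0 lists at E17.5 (8 at an unadjusted p below 0.05, 24 by fry), 0 after lesion (2 and 17 by fry) and 3 in culture.

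Leaving out each library in turn gave 3648 to 4437 genes higher and 3664 to 4667 lower at E17.5, 2398 to 2828 and 2162 to 2924 after lesion, 3225 to 4228 and 3281 to 4195 at 36 h, and 5944 to 8333 over time. The count of 8333 came without replicate 1 at 12 h. The opposite sets held 1192 to 1535 and 893 to 1134 genes. Cacna2d2 changed by 1.39 to 1.83 at E17.5, -0.66 to -0.50 after lesion and -1.98 to -1.63 in culture, and camera called 18 to 21, 15 to 18 and 20 to 22 lists. The count tests on whole reads, rescaling, filters, moderation and the runs chosen later stayed within 1.5 times of each count. Without libraries under 5 M reads only 1 E17.5 library stood against 3 at E12.5, assumed to vary like the others. That run says little of E17.5, and is left out of this statement for results that use E17.5. Among genes with a mean of at least 10 after sham surgery 4384 were higher and 4260 lower at E17.5. Rescaling moved the share of higher calls by about 1 percentage point. Shallow libraries limit small changes of low genes. With the library series of the lesion and sham libraries as a covariate, 2905 genes were higher and 2776 lower. No paired analysis was possible because the replicate numbers only follow the order of the sample records, and the labels state no pairs of libraries.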

Other observations

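The tests of trimmed-mean values, of lost nociceptors and of a lower neuron share, and all regroupings of libraries, were chosen after the result was seen, while the 2 spinal cord tests and the depth test of nociceptors had been written first. Many genes of spinal cord cell classes were lower at E17.5 than at E12.5. The homeobox gene Uncx had a mean of 550.3 at E12.5, Gad2 390.5, the interneuron factor Tal1 375 and Barhl2 355. Of the tested markers not looked at before, 5 of 6 of ventral interneurons, 3 of 4 of motor neurons, 3 of 5 of ventral progenitors, 3 of 3 of inhibitory neurons, 2 of 2 of dorsal interneurons and 1 of 2 of dorsal progenitors were called lower by limma. Shh (112 against 104.6 at E12.5) and Slc5a7 (274 against 234) were not called, nor were Olig2 and Vsx1. Replicate 3 at E12.5 was lower than replicates 1 and 2 in Fgf15 (194 against 804 and 632) and Slc32a1 (128 against 317 and 342), but higher in Irx1 (358 against 235 and 248) and En1 (179.5 against 115 and 94.4).

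Genes of DNA synthesis and of mitosis were also counted in culture, without a test between them. Of 24 DNA synthesis genes 16 rose between 6 and 36 h (median log2 change 1.35), and of 16 mitosis genes 5 rose and 1 fell (0.41), the fall being that of the spindle motor Kif11, where 3794 of all 15006 genes rose. Endothelial markers had a higher mean change than Schwann cell markers (difference of means 1.49, 20 against 18 genes, permutation p = 2.0e-05). The permutation shuffled genes, which are not independent (estimated correlations within the lists 0.51 and 0.47). Its p-value therefore does not measure the spread between libraries. These lists and their tests belonged to a 4th pattern, the rise of cell cycle and endothelial transcripts. It was taken out of the weighing after its values had been seen, to keep to 3. The question of dividing cells was left undecided. A test of the nociceptor list below against general neuron markers (difference of means -2.32, 17 against 17 genes, permutation p = 8.0e-05) was set aside after its value had been seen, since that list had been made from falls already seen in part. It shuffled genes as well.

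The first pattern was a set of 69 genes with 1 E12.5 value of at least 50 and another more than 20 times lower, against 0 to 18 such genes in the other groups. Of their 110 low values 106 (96.4%) equalled the 20% trimmed mean of all 24 libraries rounded down to whole reads, and at most 2 equalled a value shifted by a few reads. Many of these matches were under 5 reads. With the rule set after an earlier scan, which asked for at least 5 reads, 68 genes held such values, against at most 1 after a shift. For these values that argues against a different tissue as their source. Among the 68 were Hoxb9 (16889, 14359 and 418), Neurod1 (23.6, 23.8 and 851) and Pax2 (445, 6.42 and 6.49). In Fbn2, Twist1, Hes5, Dcc and Pax3 all 3 values matched. Of the 50 tested 15 were called higher and 2 lower at E17.5. All 15 called higher held such values in all 3 E12.5 libraries, so no other E12.5 value stands behind these calls. If the values were replaced, the direction of these changes is not known. The 2 called lower, Foxf2 and Gldc, held such a value in replicate 3 only. Replacement of outlying counts before deposit, as DESeq2 does, is a possible explanation, but the tool is not stated, and matches under 5 reads could not be told from chance.

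The second pattern was the presence of spinal cord type genes at E12.5. Spinal cord tissue beside the ganglia predicted that markers not looked at before would fall together, and 17 of 22 were lower at E17.5 with a median of -3.76, while 1 was called higher (Pax3, where all 3 values matched a trimmed mean). Lower depth at E17.5 was argued against, since 96.3% of the 27 calls stayed after thinning. Some spinal cord tissue in the E12.5 libraries stays possible, but the protocol names cell sorting. A change of these genes with age within the ganglia was not tested and stays open.

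The third pattern was the fall of non-peptidergic nociceptor transcripts in culture, in a list made after several of its values had been seen, without Chrna6, Ctxn3 and Grik1, which had been picked from the falls. Equal loss of these neurons predicted 1 common fall, if the members are expressed in them alone, which was not checked. The 17 members did not fall alike. Their median was -3.33 (14 lower), with an SD of 1.93 and a range from -6.23 for Mrgprd to 0.10 for P2rx3. Ret (11662 to 11126) and Gfra1 (6094 to 5557) were not called. The rule asked whether the steepest fall lay more than the SD of the members from the median. In nearly any list of this size it does, so the rule cannot decide on equal loss. A lower share of neurons as the whole cause predicted that markers of other cells rise alike. Endothelial and Schwann cell markers, lists fixed before the data were examined, moved apart (two-sided permutation p = 2.0e-05, genes not independent). These markers can move apart whatever the share of neurons does, so the test cannot decide on that share. Of 17 general neuron markers 1 rose, 8 fell and 8 were not called (median log2 change -0.54). Depth was argued against, since 100% of the 14 calls stayed after thinning. Loss of the cells, a lower share of neurons and lower transcription per cell stay open. After lesion Gfra1 rose (log2 change 1.38, limma adjusted p = 1.8e-06) and Mrgprd fell (-0.89, limma adjusted p = 0.00425).

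Libraries were also regrouped, and the counts repeated. For E17.5 and E12.5 the true grouping gave 9160 changed genes and the 9 other splits at most 0 by limma (7 to 210 genes at an unadjusted p below 0.05), so 1 of 10 splits reached the count. For lesion and sham it gave 5990 and the others at most 0 (70 to 389 at an unadjusted p below 0.05), again 1 of 10. With 10 splits no share can fall below 0.1. For lists, 1 of 10 splits reached the 19 called at E17.5 (others 11 to 18) and 3 of 10 the 16 called after lesion (others 7 to 17). Camera at the preset correlation thus called many lists in splits where limma called 0 genes. These numbers of lists alone do not set the true grouping apart. In culture 1 of 100 splits reached 6859 genes changed over time (highest other 4237) and 1 of 100 reached 7589 between 36 and 6 h (highest other 2341). For the 21 lists called in culture 5 of 100 splits did (highest other 24), so chance was not excluded for that number. For the 2618 genes with opposite changes at E17.5 and after lesion 1 of 100 combinations did (highest other 0), but the other splits call 0 genes, so this follows from the counts above and says nothing of the directions.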
